A study of Mus musculus with 8 samples.

How the data were processed

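RNA was extracted with TRIzol from small intestinal crypts of C57BL/6N mice 3 days after irradiation and sequenced as 8 libraries, 4 from wild-type mice and 4 from mice without the miR-29ab1 locus, per the labels. Each library's genotype and replicate number came from its label, and each column of the table was matched to its library through the short name that the label and the column share. HISAT2 and DESeq2 are named in the submitters' processing notes, without a role or a version. The program that counted the reads, the genome build, the annotation, the strandedness of the library kit and the radiation dose are not given in the sources used here.

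The deposited table held 17634 genes, named by symbol and NCBI gene number, and 17522 of those numbers were found in the reference gene table. The authors gave a read count per gene and library, per the file headers. Between 8.04 and 9.18 percent of these values were not exactly whole, so the deposited values were taken to be estimated counts from a method that shares reads between genes, and were rounded to whole numbers. The second set of deposited columns, whose header gives no unit, was taken to be FPKM, because the ratio of each value to its count followed the reciprocal of the library total to within 1.04 percent. The authors' group averages were not used. Totals ran from 10719668 to 16231099 counts per library in wild type and from 9481201 to 14612798 in the knockout. No library was a repeat of another, since the closest pair of a group, wild-type replicates 1 and 2, still differed by 6.04 times the variance that sampling alone gives per gene.

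Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest) with genotype as the sole term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are knockout over wild type, levels are CPM with TMM factors, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Tested on simulated counts of the same libraries (12648 genes), this test recovered 6 percent of genes changed by 1.5-fold, 52 percent at 2-fold, 80 percent at 4-fold and 98 percent at 8-fold, with 3 false calls among 12449 unchanged genes. The simulation changed 50 genes at each fold and drew genes independently, while 47.3 percent of genes were called in the data. The threshold on the unadjusted p was therefore looser in the data, and these shares do not describe the main test. Nothing in the labels beyond the sample names says how the animals were housed, bred or processed, so p-values measure the spread between these 8 samples.

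Gene lists for the cell types of the crypt, for other cells such a preparation could hold, and for metabolism, cell cycle, radiation response and miR-29 targets were fixed before the data were examined, and so were the tests, the rule for naming genes and most alternatives. The 42 lists comprised 18 of cell types and 24 of pathways. The 35 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over all 35. Camera with an estimated correlation, fry, 10000 random lists matched on expression and an exact permutation test of each list's mean per library were run beside it; with 4 libraries against 4 there are 70 assignments, and the smallest two-sided p is 0.029. The genes named are the 8 with the smallest p in each direction with a mean of at least 50 counts and no overlap between groups (predicted genes left out), up to 3 members of each list with the smallest p, and a fixed set (Lgr5, Olfm4, Mki67, Cdkn1a, Cpt1a, Ppara and the 4 miR-29 genes). Some genes that this rule takes, 1 of the fixed set among them, are not reported here and are not in the counts of named genes. Other members of a list are named where its count of calls was 5 or fewer in a direction, and these, like the genes of the lists added later, were chosen after their values were seen.

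Seed matches of miR-29 (TGGTGCT) were counted in the longest annotated 3′ UTR of each gene in GENCODE M21 on GRCm38, which 12677 of the 12908 tested genes had. For each library, the mean of the site genes was compared with that of genes without a match in the same cells of UTR length (10 bins) and expression (5 bins). In simulated data a shift of 0.2 was estimated as 0.2.

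Deviations from the group means were compared between libraries with the same replicate number. Same-numbered libraries correlated at 0.31 to 0.52, differently numbered ones at −0.48 to 0.45, and 7 of the 8 libraries correlated best with their own number, so the numbers were taken to pair the samples. The labels do not say what a number marks. The summed counts of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were 3 and 1 in replicate 4 of wild type and knockout and 1285 to 2061 in the other 6 libraries, so replicate 4 differs from the rest in the same way in both groups. The fit with the replicate number as a block is given beside a result where it changes a call. Except where pairs are named, the exact permutation tests take the libraries as unpaired, and 4 pairs would allow no p under 0.125.

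The other alternatives were DESeq2 size factors, upper-quartile factors, no filter, a mean of at least 50 counts, the Wald test of DESeq2 1.42.0, limma-voom, the robust form of the test, other thresholds, and each library left out in turn. After the data had been seen, total-count scaling, limma on log2(FPKM + 1), the enterocyte score as a covariate, and fits of subsets of libraries were added. So were 7 further gene lists, tested in the same way but with adjustment over these 7 alone.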

Results

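The series profiled gene expression in small intestinal crypts, the pockets at the base of the villi that hold stem cells, Paneth cells and dividing progenitors, 3 days after irradiation. The series title places the question in intestinal stem cell fate and energy metabolism through fatty acid oxidation. Crypts of 4 wild-type mice were compared with crypts of 4 mice lacking miR-29ab1, the locus of the microRNAs miR-29a and miR-29b-1. Libraries held 9481201 to 16231099 counts, and 12908 genes were tested. The 10 most abundant genes took 4.69 to 5.12 percent of counts in wild type and 6.02 to 9.66 percent in the knockout. The series holds irradiated crypts alone, so each difference is one of genotype after irradiation.

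The deleted genes, Mir29a and Mir29b-1, are annotated as miRNA genes on the minus strand of chromosome 6 (31062660 to 31062747 and 31063023 to 31063093, GENCODE M21 on GRCm38). Neither they nor their relatives Mir29b-2 and Mir29c on chromosome 1 were listed in the table, so the genotype labels could not be checked by the targeted gene. The first principal component, with 64.7 percent of the variance, placed all 4 knockout libraries on one side (29.6 to 82.1) and all 4 wild-type libraries on the other (−86.6 to −35.7).

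As lists tested by camera with a preset correlation, transcripts of enterocytes, of tuft, goblet and enteroendocrine cells and of lipid oxidation were higher in knockout crypts, and those of cell division were lower; no list call held with an estimated correlation (lowest camera adjusted p = 0.62). Of the 12908 genes, 6105 differed between genotypes in the quasi-likelihood test of edgeR, 3129 higher and 2976 lower in the knockout. The large changes were mostly increases: 618 genes rose and 19 fell by at least 4-fold. In 5856 genes (45.4 percent) the groups did not overlap, against 2.86 percent by chance. The count was 6137 without the 3 libraries with the highest fibroblast scores, and 4692 in replicates 1 to 3 alone, the libraries with Y-linked transcripts (1 library per genotype lacked them, too few for a test). Scaled by total counts, 6100 genes differed but 2089 were higher and 4011 lower, because that scaling put the median log2 fold of all tested genes at −0.23, from 0.034.

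Among genes with the smallest p, Slc7a8, an amino acid transporter, rose 12.1-fold from 15.7 ± 4.15 to 189 ± 61.2 CPM (SD, n = 4 per group). Cd36, a fatty acid translocase, rose 25.4-fold from 2.56 ± 1.28 to 63.5 ± 19.1 CPM. The choline kinases Chka and Chkb rose 4.05-fold and 3.11-fold, and the procollagen protease Bmp1 rose 5.24-fold from 7.72 ± 1.05 to 40.4 ± 8.25 CPM. The kinase scaffold Ksr1 (3.15-fold), the helicase Ddx60 (4.42-fold) and the phosphoinositide phosphatase Inpp4a (2.42-fold) completed the 8 higher genes. Of the 8 lower genes, 4 belong to cell division: Birc5 (survivin) fell 2.46-fold from 101 ± 7.22 to 41.2 ± 5.71 CPM, and the checkpoint kinase Bub1, the kinase Melk and the PCNA-binding factor Pclaf fell 2.69-fold, 2.36-fold and 2.63-fold. The tRNA methyltransferase Trmt10a, the Polycomb-associated Epop, the antiviral tetherin gene Bst2 and Mpzl1 fell 2.68-fold, 3.77-fold, 2.35-fold and 2.10-fold. Called genes named here and below had edgeR adjusted p-values from 0.00104 to 0.0440.

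Transcripts of differentiated enterocytes were higher throughout. All 25 enterocyte markers rose (25 adjusted over the list alone), with a median log2 fold of 3.17. The brush-border lactase Lct rose 27.5-fold from 26.9 ± 16.8 to 738 ± 318 CPM (SD, n = 4), and the disaccharidase Mgam and the microvillus protein Vil1 were higher by 1.76 and 1.75 on the log2 scale. The list was past the threshold (camera adjusted p = 3.3e-09; p = 0.19 with an estimated correlation). Of 15 ileal genes, 14 rose, among them the bile acid binding protein Fabp6 (56.9-fold), the hormone Fgf15 (5.31-fold) and the vitamin B12 receptor Cubn (26.7-fold; camera adjusted p = 1.6e-05, and p = 0.16 with an estimated correlation). Of 12 genes of the proximal small intestine, 8 rose, including Fabp1 (12.6-fold) and Adh6a (8.72-fold), with log2 folds in the list from −1.14 to 4.78 (camera adjusted p = 0.023, and p = 0.11 with an estimated correlation). Lct, Fabp1, Apoa4, Rbp2 and Slc2a5 among the 8 are also on the enterocyte list, so their rise is not separate evidence on the proximal end. Counts for the ileal and proximal lists were the same adjusted over the list alone. Within wild type the enterocyte score spread from −3.32 to −0.64 on the log2 scale around its overall mean, and within the knockout from 0.79 to 2.38.

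Transcripts of tuft, goblet and enteroendocrine cells were higher as lists. The enterocyte score as a covariate ended the goblet and enteroendocrine calls (camera adjusted p = 0.194 and 0.0547) and turned the enteroendocrine median to −0.164. Of the variance of that score 78 percent lay between the groups. Enterocyte content and genotype therefore cannot be told apart in this fit, here or for the lists below. Of 17 tuft cell genes, 13 rose (15 adjusted over the list alone), including the taste channel Trpm5 (4.78-fold), the kinase Bmx (4.73-fold) and the lipoxygenase Alox5 (2.29-fold; camera adjusted p = 1.7e-05, and p = 0.041 before adjustment, 0.62 after, with an estimated correlation). Of 19 goblet cell genes, 11 rose and Foxa1, a secretory transcription factor, fell 2.07-fold (12 and 2 adjusted over the list alone). Klk1 and Ramp1 rose 1.96-fold and 2.54-fold (camera adjusted p = 0.016; p = 0.14 with an estimated correlation). Of 22 enteroendocrine genes, 9 rose (8 adjusted over the list alone), among them somatostatin, Sst (2.55-fold), ghrelin, Ghrl (2.42-fold), and Reg4 (2.82-fold; camera adjusted p = 0.0057, and p = 0.37 with an estimated correlation). The enteroendocrine median, 0.73, was 0.44 without wild-type replicate 4. Paneth cell genes were not past the threshold as a list (5 of 22 higher, also adjusted over the list alone; camera adjusted p = 0.11), but were without knockout replicate 3 (camera adjusted p = 0.008). The 5 were Guca2b, a guanylin-family peptide that other epithelial cells also make, which rose 11.7-fold, and the defensins Defa20, Defa21, Defa22 and Defa26, whose near-identical copies share reads. Defa26 and Defa21 had log2 folds of 1.43 and 1.17, which became 0.89 and 0.77 without knockout replicate 2. The call of Defa21 was lost without wild-type replicate 3 or 4 or knockout replicate 1 (edgeR adjusted p = 0.0504, 0.0515 and 0.0545).

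Stem cell and Wnt transcripts were lower. The Lgr5+ stem cell and Wnt lists share Lgr5, Ascl2, Axin2, Rnf43, Znrf3 and Tnfrsf19. Neither list was past the threshold with the enterocyte score as a covariate (camera adjusted p = 0.126 and 0.734). Of 19 markers of Lgr5+ crypt base stem cells, 10 fell and none rose (11 adjusted over the list alone). Lgr5 itself (NCBI gene 14160) fell 1.96-fold from 28.6 ± 4.63 to 14.6 ± 6.18 CPM (SD, n = 4), Ascl2, a stem cell transcription factor, 2.67-fold, Igfbp4 2.64-fold and Cdca7 2.03-fold. The list was past the threshold (camera adjusted p = 0.0018; p = 0.24 with an estimated correlation). Olfm4, another stem cell marker, was not called, at 258 ± 169 in wild type and 358 ± 168 CPM in the knockout (edgeR adjusted p = 0.413); without wild-type replicate 3, which stood at 512 CPM, it was higher by 1.04 on the log2 scale (edgeR adjusted p = 0.0431). Of 16 Wnt targets, 9 fell and 1 rose (10 and 2 adjusted over the list alone), with the Eph receptors Ephb2 and Ephb3 down 1.90-fold and 1.93-fold and Apcdd1, a Wnt inhibitor, higher by 2.51 on the log2 scale (camera adjusted p = 0.011; p = 0.27 with an estimated correlation). Reserve stem cell genes fell in 4 of 7, namely Lrig1 (2.05-fold), Bmi1 (1.26-fold), Mex3a (2.02-fold) and Hopx (4 also adjusted over the list alone). The list was not past the threshold (camera adjusted p = 0.061), but was with the replicate block (camera adjusted p = 0.0457), without a low-count filter (0.0286) and without knockout replicate 2 or 4 (0.0383 and 0.0372). The calls of Bmi1 and Mex3a were lost without wild-type replicate 4 and replicate 3 respectively (edgeR adjusted p = 0.0626 and 0.0638).

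Proliferation and repair genes fell as whole lists. All 26 G2 and M phase genes and all 24 S phase genes fell, with medians of −1.25 and −1.12 on the log2 scale, and 25 of 29 DNA repair genes fell (26, 24 and 27 adjusted over the lists alone). Mki67, the proliferation antigen (NCBI gene 17345), fell 2.39-fold from 422 ± 122 to 177 ± 67.8 CPM (SD, n = 4), the kinesin Kif2c 2.45-fold, the replication helicase subunit Mcm3 2.42-fold, cyclin E1, Ccne1, 2.23-fold and the chromatin assembly factor Chaf1b 2.18-fold. The recombination factor Rad54l fell 2.75-fold and the DNA ligase Lig1 2.18-fold. Camera adjusted p-values were 4.7e-12, 1.6e-10 and 1.3e-09, and p = 0.11, 0.10 and 0.11 with an estimated correlation. The p53 response was mixed, 8 of 25 genes higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.11). Its median, 0.15, was −0.084 with total-count scaling. It was 0.46 with the enterocyte score as a covariate, where the list was past the threshold as higher (camera adjusted p = 0.0092). The cell cycle inhibitor Cdkn1a rose 2.05-fold from 314 ± 27.0 to 644 ± 138 CPM, Btg2 2.47-fold, Fas 2.33-fold and Trp53inp1 1.86-fold, while Tigar and Ckap2 fell.

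**Figure D1:**
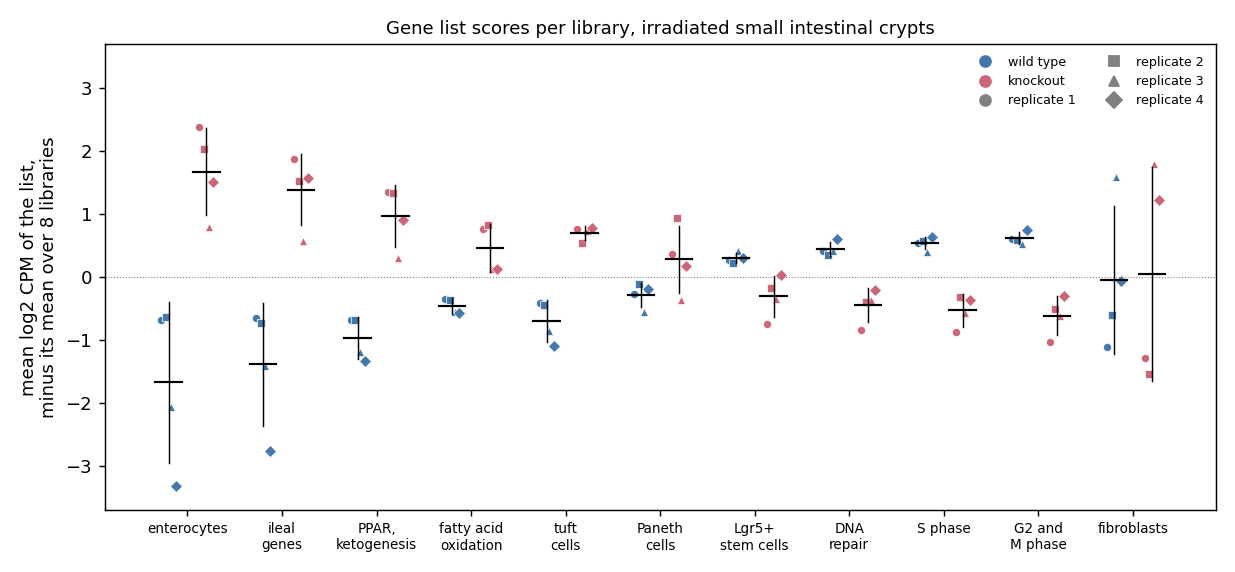
Each point is 1 library's mean log2 CPM over a gene list, minus the list's mean over the 8 libraries, for wild type (blue) and knockout (red); marker shapes give the replicate number, horizontal bars the group mean and vertical lines 1 SD. Enterocyte scores run from −3.32 to −0.64 in wild type and 0.79 to 2.38 in the knockout, G2 and M phase scores from 0.53 to 0.75 and −1.04 to −0.30, and fibroblast scores overlap.

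Transcripts of lipid oxidation, the subject named in the title, were higher in the knockout. Of 29 fatty acid oxidation genes, 18 rose and none fell (18 adjusted over the list alone), with a median log2 fold of 0.72. Acad11 rose 2.77-fold from 21.5 ± 1.70 to 59.4 ± 14.1 CPM (SD, n = 4), and the carnitine acetyltransferase Crat 3.95-fold from 20.35 ± 1.98 to 80.35 ± 28.6 CPM. Cpt1a, which loads long-chain fatty acids for mitochondria, did not rise, at 123 ± 15.7 in wild type and 101 ± 7.85 CPM in the knockout (edgeR adjusted p = 0.0758); it was called lower with upper-quartile factors, with total-count scaling and without knockout replicate 2 (edgeR adjusted p = 0.0193, 0.00605 and 0.0494). Of 19 PPAR targets and ketogenesis genes, 13 rose (14, and 1 lower, adjusted over the list alone), with a median of 2.02. Camera adjusted p-values were 1.7e-05 for fatty acid oxidation and 0.00052 for PPAR targets, and p = 0.29 and 0.095 with an estimated correlation. The lipid-sensing receptor Ppara (NCBI gene 19013) rose 11.7-fold from 4.14 ± 1.13 to 48.4 ± 28.4 CPM, its coactivator Ppargc1a 4.05-fold, and Pdk4, which diverts pyruvate from oxidation, 67.0-fold from 2.27 ± 1.15 to 148 ± 93.0 CPM.

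The fatty acid oxidation score was 0.77 and 0.82 in knockout replicates 1 and 2, and 0.12 and 0.13 in replicates 3 and 4; the median of 0.72 became 0.48 without knockout replicate 2. The same 4 libraries had enterocyte scores of 2.38, 2.03, 0.79 and 1.51.

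Other energy pathways moved in both directions or little. With the enterocyte score as a covariate the respiratory chain, TCA cycle and glycolysis lists were past the threshold as lower (medians −0.53, −0.29 and −0.40, camera adjusted p = 2.7e-06, 0.026 and 0.022). That fit cannot tell enterocyte content from genotype, and in it the fibroblast median went from 0.46 to 4.24. Of 34 nuclear-encoded respiratory chain genes, Ndufa1 rose 1.62-fold and Ndufs1 fell 1.26-fold, and the other 32 were not called, cytochrome c, Cycs, among them at a log2 fold of 0.49 (edgeR adjusted p = 0.0951; 0.0198 with the replicate block and 0.0462 without knockout replicate 3). The list had 0 calls adjusted over the list alone (camera adjusted p = 0.87; median −0.03, mean 0.03). In the TCA cycle 5 of 20 genes rose and 4 fell (5 and 7 adjusted over the list alone), with Ogdh 2.23-fold and Sucla2 1.78-fold higher, Cs and Mdh2 among the others that rose, and Pdhb 1.35-fold lower, along with Idh3a, Fh1 and Pdha1 (camera adjusted p = 0.93; the median, 0.05, was −0.226 with total-count scaling). In glycolysis 3 of 17 rose and 4 fell, also adjusted over the list alone: Pfkfb3 rose 4.61-fold and Pfkp 1.71-fold with the lactate exporter Slc16a3, while Pfkl fell 1.80-fold with Aldoa, Pgam1 and the glucose transporter Slc2a1 (camera adjusted p = 0.35; median −0.20, mean 0.01). For fatty acid synthesis 3 of 15 rose and 8 fell, also over the list alone, with Me1 and Fads2 down 2.78-fold and 2.00-fold and the regulator Mlxipl up 1.97-fold with Scd1 and Srebf1 (camera adjusted p = 0.17). For cholesterol synthesis 10 of 24 rose and 2 fell, also over the list alone, with Tm7sf2 up 2.15-fold and Idi1 among the lower (camera adjusted p = 0.13; the median, 0.20, was −0.075 with total-count scaling).

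**Figure D2:**
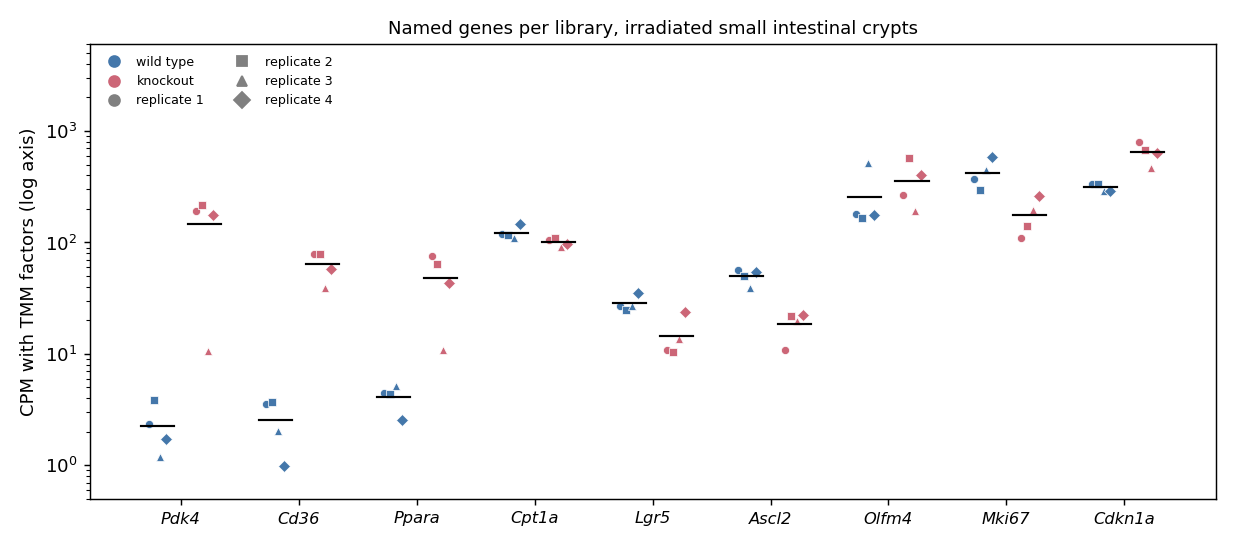
Points are CPM with TMM factors of single libraries on a log axis, wild type in blue and knockout in red, with marker shapes for the replicate number and bars for group means. Pdk4, Cd36, Ppara and Cdkn1a lie higher in all 4 knockout libraries, Lgr5, Ascl2 and Mki67 lower, and Cpt1a and Olfm4 were not called; Pdk4 in knockout replicate 3 stood at 10.6 CPM.

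Stress, immune and developmental lists were not past the camera threshold in the main fit. Immediate-early and heat-shock genes were past it as higher with the enterocyte score as a covariate (median 1.18, camera adjusted p = 0.00036). In the interferon response 14 of 29 genes rose and 2 fell, also over the list alone; the RNA sensor Ddx58 and the synthetase Oas3 rose 2.57-fold and 3.49-fold, and Bst2 and Gbp3 fell (camera adjusted p = 0.061; 0.0491 with the replicate block). This list was also past the threshold with upper-quartile factors, total-count scaling or a mean of at least 50 counts, and without wild-type replicate 1 or 2 or knockout replicate 1, 2 or 4 (camera adjusted p from 0.00746 to 0.0478). Of 19 genes of the unfolded protein and integrated stress response, 11 fell and 5 rose, also over the list alone, with the serine synthesis enzymes Phgdh and Psat1 down 2.54-fold and 2.30-fold and Ddit3, a stress-induced transcription factor, up 3.11-fold with Xbp1, Dnajb9, Herpud1 and Trib3 (camera adjusted p = 0.12). Of 20 immediate-early and heat-shock genes, 5 rose and 2 fell, also over the list alone: the differentiation factor Klf4 rose 5.10-fold, Fos, Junb, Jund and Klf6 rose with it, and the chaperones Hsph1 and Hsp90aa1 fell 2.70-fold and 2.14-fold (camera adjusted p = 0.28). In the Notch pathway 3 of 12 rose and 1 fell, also over the list alone, with the ligands Dll1 and Dll4 up 2.13-fold and 1.63-fold, the secretory fate factor Atoh1 higher by 0.59 on the log2 scale and Hes1, a Notch target, down (camera adjusted p = 0.93; median −0.24, mean 0.13). The calls of Atoh1 and Dll4 were lost with total-count scaling (edgeR adjusted p = 0.127 and 0.0875). YAP-dependent and fetal-like genes rose in 2 and fell in 5 of 21, also over the list alone, with Krt7 down 2.32-fold, along with Clu, Anxa1, Ly6a and Anxa3, and Cxadr and Birc3 up 1.95-fold and 1.70-fold (camera adjusted p = 0.20; 0.0375 without knockout replicate 3). The call of Birc3 was lost with total-count scaling (edgeR adjusted p = 0.0788). Epithelial defence genes rose in 3 and fell in 2 of 19 (2 and 1 over the list alone), with the antibody transporter Pigr up 2.06-fold along with Reg4 and Lcn2, and Sprr2a3, one of several near-identical copies, down 2.74-fold with Sprr2a1 (camera adjusted p = 0.92; median −0.20, mean 0.16).

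Transcripts of connective tissue were high in 3 libraries. Fibroblast scores were 1.59 in wild-type replicate 3 and 1.79 and 1.22 in knockout replicates 3 and 4, and −1.54 to −0.06 in the other 5 libraries. Of 14 fibroblast genes 1 was called, the growth factor receptor Pdgfrb, 3.30-fold higher at 1.37 ± 0.864 and 4.53 ± 1.74 CPM (SD, n = 4 each; 0 adjusted over the list alone; camera adjusted p = 0.92). Its call was lost without wild-type replicate 1 or knockout replicate 4 (edgeR adjusted p = 0.0553 and 0.0591). Col6a1 and the fibronectin gene Fn1 had log2 folds of 1.14 and −1.04 (edgeR adjusted p = 0.335 and 0.293), and Fn1 was called lower without knockout replicate 3 and with limma-voom (edgeR adjusted p = 0.00957, limma-voom adjusted p = 0.0467). Of 8 endothelial genes Egfl7 fell 2.26-fold (1 adjusted over the list alone; camera adjusted p = 0.92; median 0.73, and 0.021 without knockout replicate 4). Pecam1 and Lyve1 had log2 folds of 0.92 and 0.56 (edgeR adjusted p = 0.124 and 0.152; 0.032 and 0.0433 with the replicate block).

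Of the immune lists none was past the camera threshold, and Cd14 and Lcn2 were the called genes. T and intraepithelial lymphocyte genes were called in 0 of 15, also adjusted over the list alone, with a median log2 fold of 1.22 (camera adjusted p = 0.11; 0.0192 with the replicate block, 0.0257 with total-count scaling, and 0.0383 and 0.0143 without knockout replicates 2 and 4). Without knockout replicate 3 the median was 0.443, and Cd4 and Lck had log2 folds of 0.443 and 0.513. Cd8b1, Cd4 and the kinase Lck had log2 folds of 1.43, 1.56 and 1.34 (edgeR adjusted p = 0.0814, 0.111 and 0.116; 0.00539, 0.0486 and 0.0298 with the block), and Cd8b1 was called without knockout replicate 4 (edgeR adjusted p = 0.0382) and by DESeq2 (adjusted p = 0.0417). Of 7 MHC class II genes 0 were called, also adjusted over the list alone (camera adjusted p = 0.42). The list was past the threshold as lower with the enterocyte score as a covariate (median −1.86 against 0.44 without it, camera adjusted p = 0.0012). H2-Aa, H2-Ab1 and H2-Eb1 had log2 folds of 1.58, 1.12 and 0.50 (edgeR adjusted p = 0.0766, 0.163 and 0.476), and the first and second were called with the block (0.00879 and 0.0151), and H2-Aa without wild-type replicate 4 (edgeR adjusted p = 0.0333). Of 13 macrophage genes Cd14, an endotoxin co-receptor, fell 1.54-fold (0 adjusted over the list alone; camera adjusted p = 0.52). Cd68 and Fcer1g had log2 folds of −0.58 and 0.96 (edgeR adjusted p = 0.303 and 0.247), and Cd68 was called lower without knockout replicate 3 (edgeR adjusted p = 0.0329).

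Of 6 neutrophil genes Lcn2, which epithelium also makes, was called, 2.71-fold higher (0 adjusted over the list alone; camera adjusted p = 0.20 for the list, which had a median of −1.34 and was past the threshold at 0.0148 without knockout replicate 3). The call of Lcn2 was lost without any one of the wild-type libraries or knockout replicates 1 and 4 (edgeR adjusted p from 0.0565 to 0.116) and with the block (edgeR adjusted p = 0.0586), upper-quartile factors, total-count scaling and limma-voom (adjusted p = 0.0514, 0.0923 and 0.0844), and its log2 fold of 1.44 became 0.73 without knockout replicate 4. The neutrophil receptors Cxcr2 and Csf3r had log2 folds of −1.82 and −2.21 (edgeR adjusted p = 0.0772 and 0.132). Both were called lower with the block (edgeR adjusted p = 0.00684 and 0.00448) and with limma-voom (adjusted p = 0.0342 and 0.0215). They were also called lower without knockout replicate 3, at log2 folds of −3.24 and −5.43 (edgeR adjusted p = 0.00248 and 0.00108), where the list median was −3.14.

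The remaining lists were too small to test. Mylk, a smooth muscle kinase, rose 2.33-fold, and Acta2 had a log2 fold of −0.13. Cidec, a lipid droplet protein on the adipocyte and PPAR lists, rose 7.47-fold, and Pnpla2 and Fabp4 had log2 folds of 0.45 and 0.085 (edgeR adjusted p = 0.0837 and 0.954; Pnpla2 was called with the block, 0.0184, and without knockout replicate 3, 0.0235). Ret, a receptor of enteric neurons, rose 1.79-fold, a call lost with total-count scaling (edgeR adjusted p = 0.0923). Of the plasma and B cell genes, Jchain, Cd79b and Derl3 had log2 folds of −0.59, −0.58 and 0.13, and of the red cell genes Hba-a1, Hbb-bs and Hbb-bt had 0.50, 0.63 and 0.095, with no call. Hba-a1 was called with the block (edgeR adjusted p = 0.0436), and Hba-a1 and Hbb-bs without wild-type replicate 3 (edgeR adjusted p = 0.024 and 0.0177). Cela1, of the exocrine pancreas, had 0.088. With total-count scaling Fabp4, Derl3, Hbb-bt and Cela1 changed sign. The table held no mitochondrially encoded transcripts, so that list had 0 members.

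Known miR-29 targets were not past the camera threshold, either as collagen and matrix genes or as targets outside the matrix. Of 15 collagen and matrix targets 0 were called, also over the list alone (median log2 fold 0.54; camera adjusted p = 0.70). The median was 0.097 without knockout replicate 3 and 1.416 without wild-type replicate 3. Sparc, Col4a1 and Col15a1 had log2 folds of 1.75, 1.30 and 1.09 (edgeR adjusted p = 0.146, 0.101 and 0.0767). Sparc and Col4a1 were called with the replicate block (edgeR adjusted p = 0.00511 and 0.0269), Sparc without wild-type replicate 3 (0.0442), and Col4a1 and Col15a1 without knockout replicate 2 (edgeR adjusted p = 0.0355 and 0.0392). The score of this list was 0.84 in wild-type replicate 3 and 1.70 and 1.28 in knockout replicates 3 and 4, the libraries with the highest fibroblast scores, and −1.17 to −0.07 elsewhere; the lists share Col1a1, Col1a2 and Col3a1. Of 25 targets outside the matrix 8 rose and 2 fell (8 and 1 over the list alone), with the growth factor Vegfa up 3.77-fold, the RNA-decay factor Zfp36 2.37-fold and Narf 3.06-fold, and Dnmt3b and Tdg, of DNA methylation and demethylation, lower (camera adjusted p = 0.16; fry adjusted p = 0.019; random-list adjusted p = 0.41). The score of these 25 genes was higher in the knockout by 0.35 on the log2 scale (exact permutation test, p = 0.029), but by 0.09 with total-count scaling (exact permutation test, p = 0.77), where the median went from 0.344 to 0.071. With the enterocyte score as a covariate, of whose variance 78 percent lay between the groups, both target lists were past the threshold as higher (camera adjusted p = 0.00036 for the matrix and 0.0043 for the others). So was the fibroblast list, at a median log2 fold of 4.24 against 3.42 for the matrix targets (camera adjusted p = 0.0015).

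Across the transcriptome, 2136 tested genes carried a miR-29 seed match in the 3′ UTR and 10541 did not. Of the first, 23.6 percent were higher and 22 percent lower, and of the second 24.5 and 23.5 percent. Per library, site genes minus matched genes, each centred on its mean over the 8 libraries, gave 0.010 ± 0.005 in wild type and −0.010 ± 0.034 in the knockout on the log2 scale (SD, n = 4 each). The difference, −0.019, was within the spread between libraries (exact two-sided permutation test, p = 0.34; p = 0.375 for the 4 pairs, which allow no p under 0.125). Of 51 control 7-mers made of the same bases, 33 gave a difference at least as high, with a range from −0.061 to 0.089, and 19 of the controls reached the smallest exact p, 0.029. The highest control was the reversed 7-mer, which alone holds CG and matched 393 genes. The next highest stood at 0.049.

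**Figure D3:**
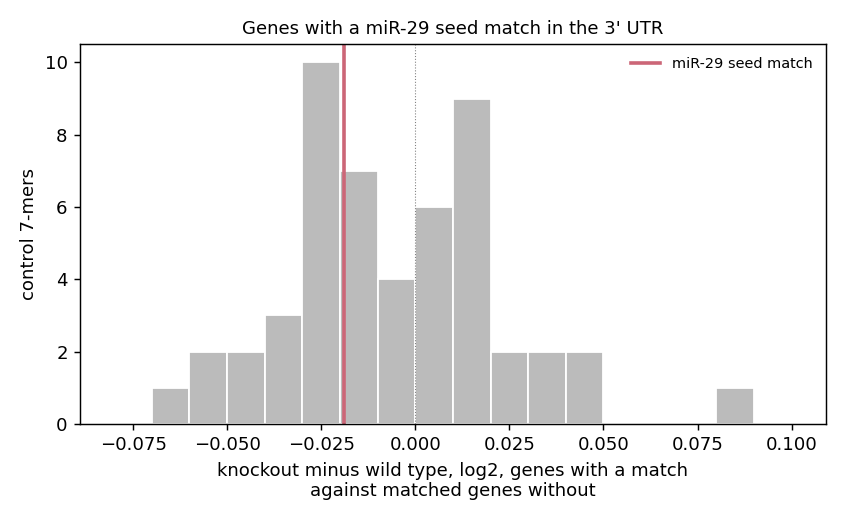
The histogram counts 51 control 7-mers by the knockout minus wild-type log2 difference of genes with a match in the 3′ UTR against genes without, matched on UTR length and expression, and the red line marks the miR-29 seed match. The seed match, at −0.019, lies inside the range of the controls, from −0.061 to 0.089 (to 0.049 without the reversed 7-mer).

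Of the 13 lists past the threshold, 8 were higher and 5 lower, and all 13 had the smallest exact p in the permutation test of library means, 0.029. This p is not adjusted, and 18 of the 35 lists reached it. With an estimated correlation none of the 13 calls held, at a lowest adjusted p of 0.62; 1 list, tuft cells, was at an unadjusted p under 0.05. By fry, 18 lists were past the threshold: 12 of the 13, without enteroendocrine cells (fry adjusted p = 0.096), and reserve stem cells, fatty acid synthesis, miR-29 targets outside the matrix, the p53 response, the interferon response and the stress response. Against random matched lists 15 were past it: 11 of the 13, without goblet and enteroendocrine cells (random-list adjusted p = 0.061 each), and reserve stem cells, lymphocytes, neutrophils and YAP-dependent genes. With the enterocyte score as a covariate 14 lists were past the camera threshold, among them 5 of the 13, namely tuft cells, PPAR targets, DNA repair, S phase and G2 and M phase. That score is the mean of the enterocyte list, so this list could not keep its call.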

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

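The test behind these values, the gap of the highest or lowest library to the nearest other library of its group relative to the range of the group, was fixed before any result, and no explanation was tested for them. It was applied to 330 groups of 4 libraries, of which chance alone would pick about 16.5, and it picked 17, so the number is near that of chance. The libraries concerned were wild-type replicate 4 in 6 cases, knockout replicate 3 in 4, knockout replicate 1 in 3, wild-type replicate 3 in 2, and wild-type replicate 2 and knockout replicate 4 in 1 each.

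Pdk4 stood at 10.6 CPM in knockout replicate 3, against 175 to 216 in the other knockout libraries. Olfm4 stood at 512 CPM in wild-type replicate 3, against 165 to 179, and Btg2 at 84.3 in the same library, against 69.4 to 70.1. In wild-type replicate 4, Sst stood at 20.4 CPM, against 49.0 to 56.9 in the rest of wild type, H2-Eb1 at 39.5 against 224 to 301, Lck at 3.85 against 13.5 to 16.7, and Fcer1g at 4.68 against 12.2 to 14.7. The same library had the lowest lymphocyte list score, −2.60 against −0.11 to 0.25, and MHC class II list score, −2.36 against −0.03 to 0.44. In knockout replicate 3, Cd4 stood at 12.7 CPM against 2.12 to 2.25, Csf3r at 9.67 against 0.172 to 0.374, and Cxcr2 at 2.89 against 0.343 to 0.374. In knockout replicate 1, Chkb stood at 71.1 CPM against 57.3 to 59.3, Hsp90aa1 at 294 against 432 to 450, and the glycolysis score at 0.12 against −0.06 to −0.04. Fabp4 stood at 3.93 CPM in knockout replicate 4, against 0.0858 to 0.199. The seed-site value of wild-type replicate 2 was 0.0026, against 0.012 to 0.0124 in the rest of wild type.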

How the results depend on the processing

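The subsets of libraries, total-count scaling, the enterocyte covariate and limma on FPKM were chosen after the data had been seen, and the other alternatives before. Of 99 named genes called, 90 stayed on the same side of the threshold in all alternatives chosen before the data were seen and with total-count scaling, and 21 of 1779 such values fell short of it, none with a change of sign. Of the alternatives outside that tally, replicates 1 and 2 alone kept 95, replicates 1 to 3 alone 91, replicates 3 and 4 alone 70, the libraries without the 3 high in fibroblast transcripts 95, limma on FPKM 92 of 97, and the enterocyte covariate 0 (lowest edgeR adjusted p 0.0523), with the sign of Sst, Ghrl and Cidec changed to log2 folds of −0.078, −0.074 and −0.43. Of 53 further called genes, named after their values were seen, 30 kept their call without each library in turn and with total-count scaling, and 23 lost it in some of these fits (edgeR adjusted p from 0.050 to 0.385): Aldh1l2, Anxa1, Arntl, Dbp, Defa20, Defa22, Dnmt3b, Fh1, Fos, Gbp3, Hes1, Hopx, Idh3a, Junb, Mdh2, Pdha1, Per1, Scd1, Slc16a3, Sprr2a1, Srebf1, Tigar and Xbp1. All 13 lists called kept their call in each of their 182 values under alternative scalings, filters, the block and left-out libraries. Outside these values, the estimated correlation ended every list call (0 lists), fry and the random lists kept 12 and 11 of the 13, replicates 1 and 2 alone kept 12 (enteroendocrine cells, camera adjusted p = 0.0842), and the enterocyte covariate kept 5. With that covariate the camera adjusted p was 0.126 for Lgr5+ stem cells and for fatty acid oxidation, 0.194 for goblet cells and for proximal genes, 0.734 for Wnt targets, 0.942 for enterocytes and for ileal genes, and 0.0547 for enteroendocrine cells. The medians of enterocytes and enteroendocrine cells became −0.03 and −0.164. The covariate is the mean of the enterocyte list itself, so the loss of that list's call was fixed in advance. The proximal list shares Lct, Fabp1, Apoa4, Rbp2 and Slc2a5 with it. The count of genes was 2212 with a fold of at least 2, 3223 in replicates 3 and 4 alone (3100 shared with the 6105), 4988 to 6328 with 1 library left out, and 7226 with the replicate block (6046 shared, 1180 gained and 59 lost). Among the genes and lists named in the text, the block changed no call beyond those printed with the results. With the enterocyte score as a covariate edgeR called 0 genes (2679 at an unadjusted p under 0.05; 0 also with DESeq2 size factors and with limma-voom), and 78 percent of the variance of that score lay between the groups. limma on FPKM called 6217 genes, 1926 higher and 4291 lower. Alternatives planned for tables without counts were not run. Results that were not called changed sign in places, and the cause was not tested. With total-count scaling the median was −0.226 for the TCA cycle, −0.075 for cholesterol synthesis and −0.084 for the p53 response, and log2 folds were −0.138 for Cela1, −0.127 for Derl3, −0.199 for Hbb-bt and −0.091 for Fabp4. Fabp4 was also −1.094 with limma-voom and −0.665 with the block. With upper-quartile factors the TCA cycle was −0.040 and Hbb-bt −0.003. Epithelial defence was 0.155 without a filter and 0.65 at a mean of at least 50 counts, where macrophages were 0.019. The seed-site difference was 0.0029 for 8-base matches, 0.0122 for at least 2 matches and 0.0895 for the reversed 7-mer (exact p = 0.0286). With 1 library left out, ranges were −0.632 to 0.187 for Acta2, −0.203 to 0.216 for Cela1, −0.073 to 0.228 for Derl3, −2.72 to 0.445 for Fabp4, −0.041 to 1.19 for Fcer1g, −0.18 to 0.59 for Hbb-bt, −0.081 to 0.117 for TCA cycle, −0.341 to 0.155 for epithelial defence, −0.283 to 1.32 for fibroblasts, −0.65 to 0.381 for macrophages and myeloid cells and −0.231 to 0.061 for nuclear-encoded respiratory chain.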

Other observations

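Except the fit of the lymphocyte list with the replicate block, the tests in this part, or the rules for reading them, were chosen after the results were seen. The gene lists added later were also written after the gene results were seen. Their counts and p-values therefore describe these data and do not test them. Of these lists only the circadian clock was fitted with the enterocyte score as a covariate. Whether the others follow enterocyte content was not tested. Genes of growth and protein synthesis were lower in the knockout. All 28 genes of ribosome biogenesis fell, with a median log2 fold of −0.96, among them Ncl (2.17-fold), Npm1 (2.21-fold) and Nop56 (2.00-fold; camera adjusted p = 2.3e-11, and p = 0.15 with an estimated correlation). Of 80 cytosolic ribosomal protein genes 57 fell and none rose, with a median of −0.51, though many have pseudogenes that can share their reads (camera adjusted p = 6.4e-12; p = 0.29 with an estimated correlation). Of 9 genes of serine and one-carbon metabolism 8 fell, among them Shmt2 (2.43-fold) and Phgdh, and Aldh1l2, a mitochondrial folate enzyme, rose 2.27-fold (camera adjusted p = 0.00074; p = 0.19 with an estimated correlation). Phgdh and Psat1 are also on the stress response list.

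Genes of phospholipid synthesis, drug metabolism and hormone response were higher. Of 14 genes of choline and ethanolamine phospholipid synthesis 10 rose, among them Pcyt2 (3.56-fold) and Pcyt1a (3.14-fold), and Mboat1 fell 1.97-fold (camera adjusted p = 0.00027; p = 0.16 with an estimated correlation). Of 12 genes of xenobiotic metabolism 10 rose, with Cyp3a11 99.3-fold and Cyp2b10 47.9-fold higher (camera adjusted p = 4.4e-05; p = 0.12 with an estimated correlation). Of 8 glucocorticoid-responsive genes 5 rose, among them Sgk1 (20.6-fold) and Tsc22d3 (10.8-fold; camera adjusted p = 0.018, and p = 0.24 with an estimated correlation). Of 16 circadian clock genes 11 rose, with Hlf 13.9-fold, Dbp 6.34-fold, Npas2 2.91-fold and Arntl 1.66-fold higher (camera adjusted p = 0.003; p = 0.15 with an estimated correlation). Ces1g of the xenobiotic list is also on the ileal list, and Per1 is on both the glucocorticoid and the clock list. Knockout replicate 3 stood apart from the other knockout libraries in several of these genes: Sgk1 at 97.1 CPM against 863 to 1592 (wild type up to 85.3), Tsc22d3 at 36.0 against 136 to 226, Cyp2b10 at 18.75 against 103 to 124, Hlf at 1.60 against 8.42 to 14.8, and Dbp at 2.59 against 13.0 to 37.0 (wild type up to 6.01). Dbp, Arntl and Per1 overlapped between the groups. The call of Dbp was lost without wild-type replicate 1 or 4 or knockout replicate 1 or 2 (edgeR adjusted p from 0.0503 to 0.0832), and that of Arntl without any library but wild-type replicate 3 or knockout replicate 4 (edgeR adjusted p from 0.0596 to 0.107). The 7 list calls held without each library in turn (highest camera adjusted p 0.0396), in the same data that the lists were written from. The clock list had 7 calls without wild-type replicate 1 or 4 or knockout replicate 1 or 2, and the ribosomal protein list 18 to 33 without any library but wild-type replicate 3 or knockout replicate 2.

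Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many genes as the 6105 found, and the highest of the others called 0. Each other split mixes the genotypes, so a difference between genotypes widens the spread within its groups and lowers its count. The count of genes stood apart from all other splits, but chance was not excluded, given the pairing by replicate number. For the count of lists the real split did not stand apart: 26 of the 35 splits passed as many as the 13 found, and the highest of the others passed 21. The 8 splits that part all 4 pairs are too few for a share under 0.05; among them the highest of the others had 0 genes and 19 lists, against 6105 and 13.

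The fall of cell cycle genes beside the rise of enterocyte genes could come from villus material that diluted crypt transcripts. Dilution lowers all crypt transcripts alike. The gap of the cell cycle score to the Paneth score without Guca2b was lower in the knockout by a difference of −1.57. Its gap to the 9 defensins of that list was lower by −1.96 (exact permutation test, p = 0.029 each, the smallest it allows). This argues against dilution as the only change. The Paneth and defensin scores were themselves higher, by 0.41 and 0.80 (exact permutation test, p = 0.23 and 0.11). A separate rise of Paneth transcripts would widen both gaps, so they do not show how much of the cell cycle fall dilution explains. The gap to the Lgr5+ stem cell score without Cdk6 was lower as well, by a difference of −0.53 (exact permutation test, p = 0.029). It stood at −0.12 to 0.04 in the knockout and 0.28 to 0.64 in wild type. This gap was left out of the test after its result was seen, because that list holds genes not confined to crypts. Single stem cell markers do not decide, since Lgr5 and Ascl2 fell by 0.975 and 1.416 on the log2 scale, Olfm4 had 0.471 and the cell cycle score fell by 1.16. Whether villus material was carried into the knockout preparations stays open, since the score of lymphocytes, which sit between villus cells, differed by 1.15 with overlapping libraries (exact permutation test, p = 0.34). By replicate number it was higher in the knockout in 3 of the 4 pairs (by 0.72, 2.32 and 1.90 in replicates 1, 3 and 4, and lower by 0.35 in replicate 2), and the lymphocyte list was past the threshold with the replicate block (camera adjusted p = 0.0192). A change in differentiation by genotype also stays open and was not tested.

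The higher expression of fatty acid oxidation and PPAR genes could follow the enterocyte content of the libraries. With the enterocyte score as a covariate, the difference in the fatty acid oxidation score went from 0.92 ± 0.20 to 0.32 ± 0.36 and that of PPAR and ketogenesis genes from 1.84 ± 0.29 to 0.75 ± 0.39 (SE, 8 libraries, without genes shared with the enterocyte list). Of the variance of that score 78 percent lies between the groups, so enterocyte content and genotype cannot be told apart for these lists, although with the covariate the PPAR list kept its camera call (median 0.64, camera adjusted p = 0.038) and fatty acid oxidation did not (0.24, camera adjusted p = 0.13). The size of the change depends on the scaling between libraries, since the fatty acid oxidation median went from 0.72 to 0.43 with total-count scaling. Scaling as the whole cause is argued against: it moves all genes of a library alike, but the fatty acid oxidation score minus the median of all tested genes was higher in the knockout by 0.85 (exact permutation test, p = 0.029), at 1.30 to 2.04 against 0.76 to 0.92 in wild type.

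The clock genes could follow enterocyte content too: their difference went from 1.13 ± 0.28 to 0.42 ± 0.54 (SE, 8 libraries) with the covariate, which cannot be told apart from genotype for the same reason. The hours of collection are not given in the sources used here. Replicate 3 of both genotypes was low in Per1 and Tef, as given above, so libraries within a genotype also differed in clock genes. Arntl and Npas2, which peak in another phase than Dbp, were higher as well, by a mean of 1.14 (exact permutation test, p = 0.029), but both arms of the clock can be higher together at some hours, so this test does not decide on a difference in time of day.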
